A study of Rattus norvegicus with 12 samples.

How the data were processed

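Messenger RNA was measured by RNA sequencing in urethral tissue from male rats. Per the labels' protocols, total RNA was extracted with a commercial kit, and poly(A)-enriched Illumina libraries were made and sequenced from both fragment ends. Poly(A) enrichment leaves most RNA without a poly(A) tail unmeasured. The authors deposited whole-number counts per gene, one column per library, with no normalization. The reads were placed on rat genome build Rnor 6.0, per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here, so reads shared between near-identical genes, overlapping genes or antisense partners could not be told apart. The table held 15 library columns, of which 12 matched the labelled samples, and 3 columns were not used here.

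The group of each library was taken from its treatment label: sham without urethral injury, urethral injury, injury with rapamycin, and injury with tetrahedral DNA nanostructure (TDN), with 3 libraries each. The labels give no dose, route, time of harvest or batch, and do not say whether the injury group received vehicle. They also do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Total counts ranged from 44765817 to 55928721 per library, so that 3 counts in a sham library correspond to 0.0542 CPM. Confidence intervals and detection floors cover counting error only.

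The table held 32623 Ensembl gene IDs, of which 9802 had no count in any of the 12 libraries. The files do not pair these IDs with gene symbols, and the gene table used for names (47357 rat genes, assembly GRCr8) matched 0 of them. The gene lists, cell type markers and rule for naming genes that had been fixed by symbol beforehand were therefore not evaluated. That rule took genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups compared and an informative symbol, and ranked them by log2 fold change. Its criteria other than the symbol left 84 genes higher and 11 lower in injury than in sham, and the first 2 in each direction are given by ID. This reduced form was chosen after the IDs were seen to lack symbols.

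Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group, 1 coefficient per group over all 12 libraries and no covariate. The filter kept 17521 genes and left out 15102. All groups shared 1 estimate of the spread, with a common biological coefficient of variation of 0.504 and 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. For a gene without a count in any sham library, the fold was computed against a floor of 3 counts per library and is a lower bound. CPM values were computed from the deposited counts, scaled by library size and TMM factor, and log2 CPM with a prior count of 2.

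Measures over whole libraries were added after the counts were seen. They are the root mean square difference in log2 CPM from the sham mean, the position on the line from the sham mean (0) to the injury mean (1), the correlation between libraries, and the share of squared distance that lies between groups. A sham or injury library was left out of its own group's mean when its distance or position was computed. Groups were compared by exact two-sided permutation tests, in which 3 libraries against 3 cannot give a p below 0.1. The share of squared distance over the 4 groups was tested over all 15400 partitions of the 12 libraries.

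Comparisons that share libraries were set beside simulations of unchanged groups. One drew independent genes from negative binomial distributions (20 draws for groups unchanged from injury, 10 for groups unchanged from sham). The other, added after the counts were seen, resampled the residuals of whole libraries and kept the genes called after injury fixed (1000 draws). Alternatives fixed before the data were examined covered DESeq2 1.42.0, limma 3.58.1 voom with and without sample quality weights, other scalings and filters, a minimum log2 fold change of 1, fits of only the groups compared, a replicate block and leaving out each library. The titles number the libraries 1 to 3 in each group without saying that the numbers pair them. Deviations from the group means of same-numbered libraries correlated over 0.1 in all 3 pairs of sham and injury (0.107, 0.138 and 0.261), so block values are given beside that comparison. This pairing comes from the data and not from the labels. In the other 5 comparisons not all 3 pairs passed 0.1, though injury and rapamycin came near (0.092, 0.156 and 0.550). Fits without the rapamycin group, or without 1 library in comparisons that do not hold it, and genes called without an injury library that then served as the only reference for a treatment, were added after the counts were seen.

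The test was run on simulated counts for injury against sham, with 17275 genes passing the filter. At the spread fitted to these libraries it recovered 1.02% of seeded changes of 1 on the log2 scale and 21.2% of changes of 2, with 0 false calls. At a dispersion scaled by 0.1 (17241 genes) it recovered 53% and 90.9%, with 9 false calls.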

Results

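The transcriptome of rat urethral tissue was compared among 4 groups of 3 libraries each. Sham tissue came from rats without urethral injury, and the other groups had a mechanical injury of the urethra that was either not treated further or followed by rapamycin or TDN. Rapamycin is an inhibitor of the mTOR kinase, and TDN is a tetrahedral particle assembled from synthetic DNA strands. The stated purpose was to describe the transcriptional changes that go with urethral injury and with TDN treatment. Total counts per library were 50727728 ± 372616 in sham, 52511530 ± 3273522 in injury, 49869721 ± 4923516 in injury with rapamycin and 50493062 ± 2018922 in injury with TDN (SD, n = 3 each). At least 1 count was found for 19080 ± 151 genes in sham, 18836 ± 203 in injury, 18450 ± 856 in rapamycin and 19052 ± 115 in TDN (SD, n = 3 each).

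The libraries within sham and within TDN resembled each other closely, with mean Spearman correlations across genes of 0.984 and 0.987. The mean correlation was 0.932 within injury and 0.904 within rapamycin. The median SD of log2 CPM over the 17521 tested genes was 0.174 in sham, 0.185 in TDN, 0.514 in injury and 0.773 in rapamycin (n = 3 libraries each). The rapamycin group had the highest SD of the 4 groups for 11215 genes. Rapamycin replicate 2 stood apart, with 17475 detected genes, an upper quartile of 391 counts against 780.5 to 978.5 in the other libraries, and a TMM factor of 0.660. Its 10 most counted genes held 7.43% of its counts (95% Wilson interval 7.43 to 7.44%). Of the squared distance between libraries, 49.0% lay between the 4 groups (exact permutation p = 0.0234 over 15400 partitions). Without sham replicate 1 the share was 46.2% (exact permutation p = 0.0749), and without sham replicate 2 it was 45.8% (exact permutation p = 0.0753). Without TDN replicate 1 it was 48.6% (exact permutation p = 0.0531), and without TDN replicate 2 it was 48.3% (exact permutation p = 0.0536). For rapamycin against injury alone the share was 14.9% (exact permutation p = 0.8), and for TDN against injury 33.5% (exact permutation p = 0.3). The other pairs of groups gave 39.5 to 50.3% (exact permutation p = 0.1, the smallest possible). Adjusted over the pairs, no permutation p was below 0.15. The share over the 4 groups therefore does not show that each group differed from the others.

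**Figure D1:**
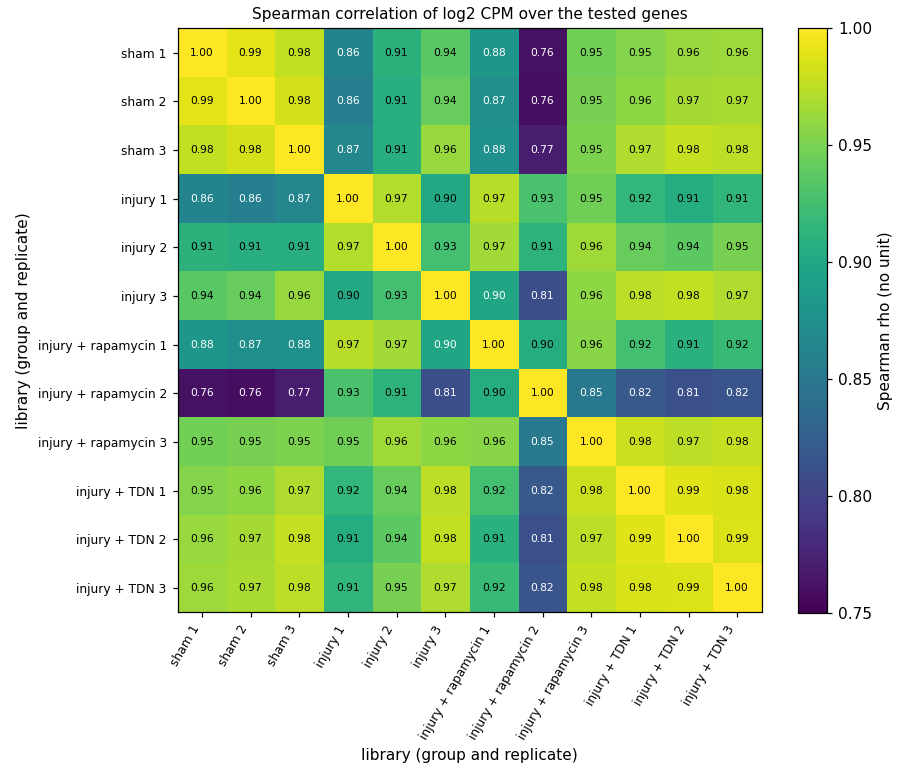
Heat map of Spearman correlations of log2 CPM over the 17521 tested genes between all 12 libraries, with libraries on both axes and rho given in each cell. The sham libraries and the TDN libraries form blocks of high correlation (means of 0.984 and 0.987), and rapamycin replicate 2 has the lowest values.

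Injury against sham asked which transcripts changed in the injured urethra. Of 17521 genes, 100 rose and 14 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The genes that rose had a median log2 fold change of 3.02, or 2.83 when the 7 of them without a count in any sham library were set at their bound, and 32 lay under 1 CPM in sham. The genes that fell had a median of -1.98, and 4 of them lay under 1 CPM in injury. These medians come from genes selected on the same libraries and are therefore inflated. At an unadjusted p under 0.05 there were 2436 genes higher and 1384 lower, and the libraries of the groups did not overlap for 42.3% of genes. Chance gives 10% on average over groupings. Genes that move together can put a single grouping far from this, and that spread was not computed.

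Among the genes that rose, ENSRNOG00000050586 had no count in the 3 sham libraries and 15.9 ± 15.2 CPM in injury (SD, n = 3), at least 294-fold higher than a floor of 3 counts per sham library (0.0542 CPM; edgeR adjusted p = 0.0301), or at least 134-fold without injury replicate 1. ENSRNOG00000050110 rose from 0.129 ± 0.223 CPM to 38.0 ± 42.3 CPM (SD, n = 3 each; log2 fold change 8.19, SE 1.52, edgeR adjusted p = 0.0438). Its sham level rests on 21 counts in replicate 3, and the other 2 sham libraries had 0 counts. The log2 fold change was 6.71 without injury replicate 1 and 13.9 without sham replicate 3, the latter against 0 sham counts. ENSRNOG00000023151 fell from 20.7 ± 2.0 CPM to 0.986 ± 0.732 CPM (SD, n = 3 each; log2 fold change -4.39, SE 0.74, edgeR adjusted p = 0.0357). ENSRNOG00000001915 fell from 54.1 ± 5.8 CPM to 6.01 ± 4.31 CPM (SD, n = 3 each; log2 fold change -3.17, SE 0.49, edgeR adjusted p = 0.0298). Rapamycin tissue held 13.5 ± 14.9 CPM of ENSRNOG00000050586, 31.5 ± 23.5 CPM of ENSRNOG00000050110, 2.79 ± 2.14 CPM of ENSRNOG00000023151 and 7.52 ± 1.53 CPM of ENSRNOG00000001915 (SD, n = 3 each). All 4 calls were lost in a fit of the 6 sham and injury libraries alone, and when any 1 TDN library was left out. With the replicate number as a block, the edgeR adjusted p was 0.0628 for ENSRNOG00000050110 (4.73e-09 to 0.194 over all alternatives) and 0.0583 for ENSRNOG00000023151 (1.30e-08 to 0.182), and 76 genes were called, of which 54 were among the 114.

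The number of genes called after injury depended on single libraries and on the tool. It was 0 without sham replicate 1, sham replicate 2 or injury replicate 1, 69 without sham replicate 3, 68 without injury replicate 2, and 2117 without injury replicate 3. Libraries in neither group, which share the estimate of the spread, mattered too: 10, 7 and 11 genes were called without TDN replicates 1 to 3, and 104, 1966 and 305 without rapamycin replicates 1 to 3. DESeq2 called 1846 genes, limma voom 162, voom with sample quality weights 9322, edgeR on the 6 libraries alone 0, and edgeR without the rapamycin group 2616. The sample quality weights were 0.433, 2.10 and 0.204 for injury replicates 1 to 3, so the 9322 leaned mostly on injury replicate 2. The excess of higher over lower genes depended on the setting too, with 1255 higher and 591 lower in DESeq2, 104 and 58 in voom, 4654 and 4668 with sample quality weights, and 1143 and 974 in edgeR without injury replicate 3.

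Over all tested genes, the root mean square log2 difference from the sham mean was 0.675 ± 0.111 for sham, 1.42 ± 0.31 for injury, 1.76 ± 0.75 for rapamycin and 0.902 ± 0.067 for TDN (SD, n = 3 each). Every injury library lay above every sham library (exact permutation p = 0.1, the smallest that 3 against 3 allow; adjusted over 18 tests p = 0.2). The injury libraries were spread widely along the line from the sham to the injury mean, at 1.31, 0.912 and 0.355, with the last value in replicate 3.

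**Figure D2:**
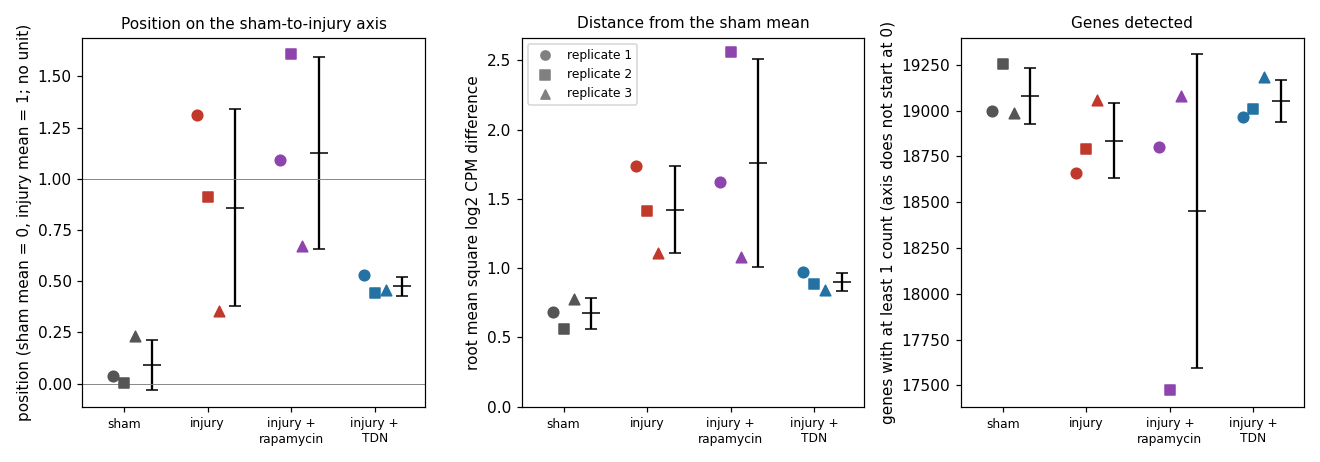
Position on the line from the sham mean (0) to the injury mean (1), root mean square log2 CPM difference from the sham mean, and number of detected genes (y axes) for each library by group (x axis). Points are libraries, with the symbol giving the replicate, and bars are the group mean and SD (n = 3); the TDN libraries lie between 0.441 and 0.528 on the line and the injury libraries between 0.355 and 1.31.

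TDN treatment of the injured urethra was compared with injury alone. The TDN libraries lay nearer to sham than the injury libraries did, at 0.843 to 0.974 against 1.11 to 1.74 in root mean square log2 difference from sham. The groups did not overlap in this distance (exact permutation p = 0.1, the smallest possible; adjusted p = 0.2). The position between sham and injury was 0.475 ± 0.047 for TDN and 0.859 ± 0.480 for injury (SD, n = 3 each; exact permutation p = 0.4, adjusted p = 0.514). The difference in position, -0.384, was 0.112 without injury replicate 1 and -0.040 without injury replicate 2.

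No single gene passed the test between TDN and injury: edgeR called 0 genes, with 294 higher and 780 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.204. DESeq2 called 42 genes (18 higher, 24 lower), limma voom 0 and voom with sample quality weights 6581 (3343 higher, 3238 lower). The excess of lower genes thus depended on the setting. The 4 genes given above were at intermediate mean levels in TDN. ENSRNOG00000050586 was at 2.99 ± 1.04 CPM and ENSRNOG00000050110 at 5.69 ± 2.64 CPM, below their injury means, while ENSRNOG00000023151 was at 6.18 ± 1.82 CPM and ENSRNOG00000001915 at 21.6 ± 8.9 CPM, above theirs (SD, n = 3 each). The edgeR adjusted p for TDN against injury was 0.649 for each of them. These genes were picked for the largest changes after injury, which can by itself place another injured group nearer to sham. Their rapamycin means also lay between those of sham and injury.

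The 114 genes called after injury were followed as a group. The 100 genes that rose after injury had a median log2 difference of 2.11 between TDN and sham, or 2.10 with bounds, and 97 of them were above all sham libraries in all TDN libraries. For 94 of the 100 the difference from sham was smaller in TDN than in injury. The 14 genes that fell after injury had a median of -0.89 between TDN and sham, and the difference was smaller than in injury for all 14. Selection on the injury libraries can raise these 2 counts. In rapamycin the difference from sham was smaller than in injury for 64 of the 100 genes and 12 of the 14. Treated groups simulated without a change from sham gave medians of 0.23 and -0.31 for genes called higher and lower, from the shared sham libraries alone (10 draws).

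The fitted TDN effect against injury had the opposite sign to the injury effect for 94.7% of the 114 genes (88.6, 93.9 and 89.5% with single TDN libraries). The injury libraries enter both effects, and unchanged treated groups simulated from independent genes gave 68.6% (66.4 to 71.5%, 20 draws). This simulated share was taken over the genes called in each draw, whose number was not kept. Lists longer than the real 114 would be selected less strongly, so 68.6% may understate the share without a treatment effect. Resampled whole libraries gave 50% with a 95% range of 16.6 to 83.3% (1000 draws). The genes were also selected on these injury libraries. The resampling kept the 114 genes as called, so its range leaves out this selection and sets no chance limit for the 94.7%. Over all 17521 tested genes the share was 85.6%, with the injury libraries still in both effects. Genes were then called without an injury library, and TDN was set against that library alone. The share was 52.9% for the 68 genes called without replicate 2. It was 52.8% for 2111 of the 2117 genes called without replicate 3, those that also passed the filter with all libraries. No gene was called without replicate 1. Replicates 2 and 3 lay nearer to sham than replicate 1 (positions of 0.912 and 0.355 against 1.31), which can lower these shares. The covariance of both effects across genes was -0.796 against a simulated -0.162 (95% range -1.39 to 0.483), a difference of -0.633. When the injury and TDN labels were exchanged in all 20 ways, 15 gave called genes and 2 of these gave a share at least as high (exact one-sided permutation p = 0.133, where 0.0667 is the smallest possible).

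**Figure D3:**
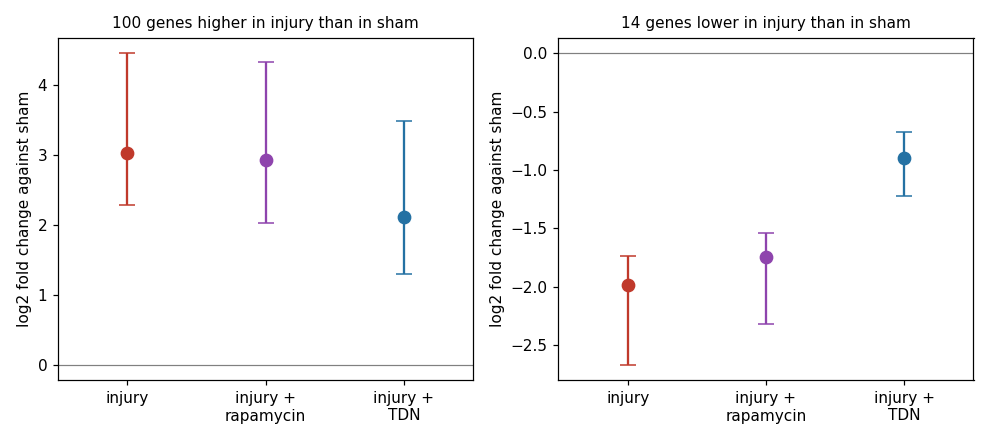
Median log2 fold change against sham (y axis) in injury, injury with rapamycin and injury with TDN (x axis) for the 100 genes higher and the 14 genes lower in injury than in sham, with bars from the lower to the upper quartile over genes. The medians for the genes that rose are 3.02, 2.93 and 2.11, and those for the genes that fell are -1.98, -1.74 and -0.89; the genes were selected on the injury libraries.

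TDN against sham asked what still differed from uninjured tissue. The edgeR test called 0 genes, with 688 higher and 242 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0658. Every TDN library lay farther from the sham mean than every sham library (exact permutation p = 0.1, the smallest possible, adjusted p = 0.2). The libraries did not overlap for 32.6% of genes, where chance gives 10% on average with a spread that was not computed. A fit of only these 6 libraries, which leaves out the more variable groups, called 617 genes higher and 376 lower. DESeq2 called 311 genes, limma voom 0 and voom with sample quality weights 1959, and edgeR called 6 without sham replicate 3, 0 to 16 without a library in neither group and 10 without the rapamycin group.

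Rapamycin treatment was compared with injury alone in the same way. The rapamycin libraries lay at 1.62, 2.56 and 1.08 from the sham mean in root mean square log2 difference, beside 1.74, 1.42 and 1.11 for injury, and the groups overlapped (exact permutation p = 0.7, adjusted p = 0.741). The edgeR test called 0 genes, with 523 higher and 244 lower at an unadjusted p under 0.05. The libraries did not overlap for 3.94% of genes, where chance gives 10% on average. Of these genes 305 were higher and 385 lower, the opposite balance. DESeq2 called 29 genes, and limma voom called 0 with and without sample quality weights; edgeR called 3 without rapamycin replicate 3.

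The genes that rose after injury had a median log2 difference from sham of 2.93 in rapamycin (2.74 with bounds), and the genes that fell had a median of -1.74, where simulated groups unchanged from sham gave 0.24 and -0.32 (10 draws). The rapamycin effect against injury opposed the injury effect for 66.7% of the 114 genes (59.6, 45.6 and 78.1% with single libraries). Unchanged groups simulated from independent genes gave 68.8% (66.9 to 72.7%), which may be an understatement for the same reason as in TDN. Resampled libraries gave 50% (95% range 16.6 to 83.3%), a range that leaves out the selection of these genes. Over all 17521 tested genes the share was 34.1%. Set against an injury library that had not entered the selection, the share was 30.9% for replicate 2 (68 genes) and 9.43% for replicate 3 (the same 2111 genes). Replicate 3 lay nearest to sham of the injury libraries, at position 0.355 beside 0.671 to 1.61 for rapamycin, which favours a low share. No gene was called without replicate 1, the farthest at 1.31. The covariance was 0.184 against a simulated -0.162, a difference of 0.347, and lay within the simulated 95% range of -1.39 to 0.483. Of the 20 exchanges of labels, 12 gave a share at least as high (exact one-sided permutation p = 0.6). The share was 38.0% of the 305 genes called without rapamycin replicate 3.

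Rapamycin against sham asked what differed from uninjured tissue after injury and rapamycin. In rapamycin tissue 1672 genes were higher and 490 lower (edgeR, adjusted p under 0.05). Their medians were 2.26 and -1.66 on the log2 scale (2.25 and -1.65 with bounds), and the same genes had medians of 1.44 and -1.23 in injury against sham and 0.54 and -0.61 in TDN against sham. Unchanged groups simulated from independent genes with shared, simulated sham libraries gave medians of 0.15 and -0.22 for both (10 draws). The simulated lists held a median of 2416 higher and 1916.5 lower genes. They were larger than the real lists, so these medians may understate the values from shared libraries alone. The 4 genes given above passed here too (edgeR adjusted p = 0.0188 for ENSRNOG00000050586, 0.0231 for ENSRNOG00000050110, 0.0350 for ENSRNOG00000023151 and 0.0215 for ENSRNOG00000001915). Of the genes called after injury, 97 of the 100 that rose and 11 of the 14 that fell were called in the same direction, where independent lists share 9.54 and 0.392. Unchanged groups simulated with shared sham libraries called at most 1 gene in 10 draws, so their lists give no chance value for this overlap. The correlation of both sets of fold changes across genes, which are not independent replicates, was 0.851 beside a simulated 0.501, and their covariance was 1.93 beside 0.247. The simulated values already hold the part from shared sham libraries, drawn at the spread pooled over the groups. The real sham libraries varied less, with a median SD of 0.174 beside 0.514 in injury and 0.773 in rapamycin. Sham deviations that move genes together were not simulated.

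The number called between rapamycin and sham was 1 without sham replicate 1 or without sham replicate 2, 20 without sham replicate 3, 79 without rapamycin replicate 1, 908 without rapamycin replicate 2 and 7249 without rapamycin replicate 3, and 422 to 3936 without a library in neither group. It was 34 in a fit of the 6 libraries alone, 731 with library size as the only scaling, 1157 without a filter, 5676 with DESeq2, 1783 with limma voom and 8440 with voom and sample quality weights. The excess of higher genes was absent in voom, with 874 higher and 909 lower, and with sample quality weights, with 4229 and 4211. The weighted fit leaned mostly on rapamycin replicate 1, with weights of 1.44, 0.074 and 0.309 for rapamycin replicates 1 to 3.

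TDN and rapamycin were also compared directly. The TDN libraries lay nearer to sham in root mean square log2 difference, with no overlap between groups (exact permutation p = 0.1, the smallest possible; adjusted p = 0.2), and their positions of 0.475 ± 0.047 lay below the rapamycin positions of 1.12 ± 0.47 (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.2). The edgeR test called 0 genes, with 1102 higher and 3158 lower in TDN at an unadjusted p under 0.05 and a smallest adjusted p of 0.161. It called 1893 genes higher and 2895 lower without rapamycin replicate 3. DESeq2 called 160 genes higher and 1417 lower, limma voom 0, and voom with sample quality weights 2941 higher and 3052 lower.

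The effects of both treatments against injury had a correlation of -0.183 across genes. The injury libraries are in both effects, and unchanged groups gave 0.496 when simulated from independent genes and 0.548 with resampled libraries (95% range -0.437 to 0.926). The covariance was -0.114 against a simulated 0.171 (95% range -0.166 to 1.10), a difference of -0.285. With different injury libraries in each effect the correlation was -0.281 (-0.691 to 0.166), and it was 0.266 without rapamycin replicate 2 and 0.218 without injury replicate 3.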

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

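Fits without the rapamycin group, or without 1 library in neither group, alternatives for measures over whole libraries, and libraries left out of the correlation of treatment effects were chosen after seeing the data, as were held-out injury libraries and bounds with 1 left out. For injury against sham, TDN against injury, rapamycin against injury, TDN against rapamycin, TDN against sham and rapamycin against sham, DESeq2 in this order called 1846, 42, 29, 1577, 311 and 5676 genes. Voom with sample quality weights called 9322, 6581, 0, 5993, 1959 and 8440. Fitting only the 2 groups compared gave 0 for injury against sham, 993 for TDN against sham and 34 for rapamycin against sham. Library size alone gave 6 for TDN against sham and 731 for rapamycin against sham, and moved the median log2 fold change of all genes in the latter from -0.05 to -0.37. No filter gave 1157 for rapamycin against sham. Without the rapamycin group, edgeR called 2616 genes for injury against sham and 10 for TDN against sham. Leaving out 1 library gave 0 to 2117 for injury against sham, 0 to 3 for rapamycin against injury, 0 to 4788 for TDN against rapamycin, 0 to 16 for TDN against sham, 1 to 7249 for rapamycin against sham and 0 for TDN against injury. Leaving out 1 library in neither group gave 7 to 1966 for injury against sham (10, 7 and 11 without a TDN library), 0 to 16 for TDN against sham, 422 to 3936 for rapamycin against sham and 0 elsewhere. The stricter filter, DESeq2's size factors and the minimum fold change stayed within 1.5 times of each count. Unweighted voom did too. Apart from fewer libraries in a fit, which also changed filter and scaling, the cause was not tested.

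The share of genes for which TDN opposed injury was 52.9% and 52.8% against injury replicates 2 and 3 when these were held out of the gene selection, 89.3% with disjoint injury libraries in the effects but all 3 in the selection, and 81.8 to 100% with 1 library left out. Both ends come from lists of 11 and 10 genes without a TDN library, and lists of 68 to 2117 gave 95.7 to 98.1%. That for rapamycin was 30.9% and 9.43% against the held-out replicates and 38.0 to 87.0% with 1 library left out, below 50% without rapamycin replicate 3. Neither has a value where no gene was called (without sham replicate 1 or 2 or injury replicate 1). The correlation of both treatment effects was -0.281 with disjoint injury libraries and -0.413 to 0.266 with 1 library left out, above 0 without injury replicate 3 or rapamycin replicate 2. The share of squared distance between groups was 45.8 to 59.6% with 1 library left out, and the position of TDN minus that of injury was -0.530 to 0.112. In both scalings, both filters and a prior count of 5, the measures over whole libraries kept their direction and their side of 0.05. The 4 genes given by ID kept their direction in all 23 alternatives and lost their call in 9 to 11.

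Over all groups, 6 of 18 same-numbered pairs correlated over 0.1 (-0.243 to 0.550), and 4 of the 6 sham and injury libraries correlated best with their own number, a hint from the data. With a replicate block, edgeR called 76 genes for injury against sham (54 shared with the 114), 2586 (1417 higher, 1169 lower) for rapamycin against sham and 0 in the other 4 comparisons. The rapamycin share was then 50% and the correlation of treatment effects was -0.031. ENSRNOG00000050110 (edgeR adjusted p = 0.0628) and ENSRNOG00000023151 (adjusted p = 0.0583) lost their injury call, where adjusted p over all alternatives ran from 4.73e-09 to 0.194 and from 1.30e-08 to 0.182.

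The skeletal muscle covariate and gene list tests were not run, for lack of gene symbols. Depth sets a floor of 0.0542 CPM in sham (3 counts per library).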

Other observations

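All tests in this part, except the regroupings of libraries, were chosen after the results they bear on had been seen. Function and cell type could not be read from the gene IDs, so no biology beyond the groups is described here.

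Rapamycin replicate 2 stood apart from the other libraries, with 17475 detected genes, a distance of 2.56 from the sham mean and a voom sample quality weight of 0.074. Lower depth is argued against, since each of the other 11 libraries thinned to its total still detected at least 1093 genes more. A skew to its very top genes is argued against too, since its 10 most counted genes held a smaller share than in any other library, by a difference of -0.426 percentage points from the lowest. Its 100 most counted genes held 28.2%, under only TDN replicate 1 (28.9%), and its TMM factor was 0.660, so a skew over more genes stays open. Its difference from sham correlated across genes with the injury difference at 0.683 or more when different sham libraries entered each (0.780 when shared), as a larger move in the same direction would give. Part of its difference lay off that direction. On the second principal component of log2 CPM, the second largest direction of variation (11.9% of the variance), it lay at -95.0. The other injured libraries lay there at -0.589 to 66.7 and sham at -42.4 to -36.2. RNA quality, dissection and a stronger injury stay open, as untested.

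Injury replicate 3 correlated better with the TDN libraries than with injury replicates 1 and 2, by 0.0614 in mean Spearman rho. An exchange of this library with a single TDN library is argued against as far as the true injury library would resemble injury replicates 1 and 2, since every TDN library correlated better with the other TDN libraries than with those, by at least 0.0363; an exchange of all 3 labels would leave this margin as it is. Over 2111 of the 2117 genes called without this library, those that pass the filter with it, it lay farthest to the injury side in 33.3%, among 3 TDN libraries with 35.9, 11 and 19.8%, where chance gives 25%. Its root mean square log2 distances to the TDN libraries were 0.857 to 0.936, above the 0.666 to 0.733 among these, so it was not a typical TDN library. Its distance from the sham mean, 1.11, also lay above the TDN values of 0.843 to 0.974. A single wrong label and a milder injury in that library both stay open. Its share of genes farthest to the injury side lay within the range of the TDN libraries, and a TDN animal may also lie apart from the others. Nearness to the TDN libraries was not peculiar to injury replicate 3. Rapamycin replicate 3 lay at root mean square log2 distances of 0.810 to 0.864 from the TDN libraries. From rapamycin replicates 1 and 2 it lay farther, at 1.08 and 2.17.

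EdgeR with all 12 libraries called no gene between TDN and sham, while injury and rapamycin both differed from sham in some genes; DESeq2 called 311 between TDN and sham, and voom with sample quality weights 1959. A spread estimate shared with more variable groups may account for this, since the 6 sham and TDN libraries alone gave 993 genes, though that fit also changes the filter and the scaling. TDN libraries nearer to sham than the injury libraries are a second candidate explanation, since the lowest injury library exceeded the highest TDN library by 0.135 in root mean square log2 difference. Both had the values they need, so the count of 0 does not show that TDN tissue equalled sham. A biological effect of TDN stays open as a hypothesis.

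Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05, and edgeR with all 12 libraries was used for each. For injury against sham the real split called 114 genes and the highest other split 0 (1 of 10 as large; 3 of the others part all same-numbered pairs as the real one does, and 6 part only 1), and for rapamycin against sham 2162 and 0 (1 of 10). For TDN against injury, rapamycin and sham the real split and the highest other split called 0 in this test (10 of 10). Other tools did call genes in these real splits. Where the real split called 0, every split was at least as large, so the 10 of 10 here and below was fixed in advance. For rapamycin against injury the real split called 0 and another called 3341 (10 of 10 as large as the real one). That split set injury replicate 1 and rapamycin replicates 1 and 2 against injury replicates 2 and 3 and rapamycin replicate 3, and points to a structure among these 6 libraries that does not follow the treatment.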
